A study of Homo sapiens with 2 samples.

How the data were processed

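Gene expression was measured on 2 Affymetrix arrays, 1 of U251 cells with the empty vector and 1 of U251 cells with TRIM45. Groups were taken from each sample's source label. Other labels of the same samples speak of human brain tissue, which conflicts with the source label, the growth protocol and the series title. The samples were treated as the cell line that the latter name, and this conflict stays a limit on every value. Per the labels, biotinylated cRNA was prepared from 100 ng of total RNA by the manufacturer's protocol. The deposited values are intensities, 1 per probe set and array, on a linear scale. MAS5 and RMA are both named in the submitters' processing notes, but which of them made these values is not given in the sources used here, nor is the scanner software. The deposited signals ran from 2.59 to 11682, and 8264 probe sets (15.1%) had exactly equal values on both arrays (tolerance 0), with a median signal of 8.08 among them. No detection calls were used, so a signal near the array median cannot be told from background. Arrays carry no read depth, and the number of arrays limits the precision.

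The platform annotation gave 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777; the last 2 kinds are unnamed here and entered no gene value. Gene identifiers of 41043 of the 41097 matched the RefSeq gene table of assembly GRCh38.p14, which changed no symbol. No genome of the probe design was used, so no coordinates are given. XIST and Y-linked genes were left out, and 1 of the 5 genes fixed for naming had no value here.

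Both arrays were scaled to 1 median (factors 1.008 and 0.992) and transformed to log2(signal + 16). A probe set was kept if the brighter array was at or above the 50th percentile of that array. The value of a gene was that of its brightest probe set by the mean over both arrays, and the difference was the TRIM45 array minus the empty-vector array. This left 12658 of 19740 genes. With 1 array per group there is no residual spread, so no test was made, and genes were described by size: 2-fold for the count over all genes and 1.5-fold for members of gene lists. The spread between probe sets was the pooled SD over genes with at least 2 probe sets past the filter, within classes of mean signal. It includes differences between isoforms. Ranges over the probe sets of a gene cover those past the filter unless stated otherwise, while means are over all probe sets of the gene, dim ones included. Gene-specific probe sets are those whose name carries no single letter before its ending, and the brightest of them stands for the gene. This rule leaves out sets marked for shared or unspecific matches, and also those marked for several transcripts of the same gene.

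Before the data were examined, 30 gene lists, the thresholds and the rule for named genes were fixed. The rule named 5 fixed genes, the 12 highest and 12 lowest genes past 2-fold whose probe sets all went the same way, and up to 2 members at each end of each list; further list members are given as examples chosen after their values were seen. For the 29 lists with at least 5 measured members, the median was placed among the medians of 10000 random lists of equal size, matched on deciles of mean signal, and called apart below percentile 2.5 or above 97.5. Such a percentile describes these 2 arrays and is not a p-value. If list members varied independently, about 1.45 of 29 lists would be called. Members of a list can vary together, so any difference between 2 cultures can call more lists than that. Of the lists, 5 lay apart as higher and 6 as lower.

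The 2-fold threshold and the list comparison were tried on simulated log2 differences of 12658 genes, with noise of SD 0.3 drawn independently for each gene. Scaling, filter, pseudocount and choice of probe set were not simulated. Of 200 changed genes, those changed by 1.5 on the log2 scale passed 2-fold in 95.0% of cases and those changed by 3 in 100.0%, while 17 unchanged genes passed. A list of 24 genes shifted by -1 was called, and 10 of 200 unchanged lists (5.0%) were called. These rates follow from the noise that was set and from the percentile limits. They say nothing on lists whose members vary together, and the noise between cultures is unknown. Alternatives tried were centring, quantile and loess normalization (span 0.3), no filter or a filter at the 75th percentile, the mean of a gene's probe sets, gene-specific probe sets alone, pseudocounts of 1 and 64, thresholds of 1.5-fold and 3-fold, probe sets all in one direction, and lists without shared members. Scaling to the hybridization spike-in controls, no scaling, a minimum signal of 100 and, for the lists, the brightest probe set over genes that have a gene-specific one past the filter were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.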

Results

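The data were 2 Affymetrix expression arrays of U251, an established human glioblastoma cell line, transduced with lentivirus. 1 array carried RNA of cells transduced with the empty vector and 1 carried RNA of cells transduced with TRIM45, which encodes a RING-type E3 ubiquitin ligase of the tripartite motif family. The design asked which transcripts differ when TRIM45 is overexpressed. Each array reported 54675 probe sets on a linear signal scale, with a median of 19.8 on the empty-vector array and 20.1 on the TRIM45 array. Because there was 1 array per group, no difference below has a replicate check or a p-value. The only internal error was the disagreement between probe sets of the same gene, which had a pooled SD on the log2 scale of 0.29 for dim genes, 0.26 for genes of middle signal and 0.23 for bright genes. It does not cover variation between cultures. All fold differences are TRIM45 against empty vector on the log2(signal + 16) scale, which understates the change of dim genes.

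TRIM45 itself was higher on the TRIM45 array with both of its probe sets. Its probe sets read 204.7 against 68.5, a log2 difference of 1.37, and 186.6 against 81.4, a log2 difference of 1.04. The mean over both was 1.20 ± 0.23 (SD, n = 2 probe sets). The probe set that stands for the gene was 2.05-fold higher, and 259 genes, TRIM45 among them, differed upward by at least as much. Which part of the transcript these probe sets read was not given, so a vector carrying only the coding sequence could be read incompletely. Of 12658 genes with signal past the filter, 288 (2.28%) were at least 2-fold higher and 383 (3.03%) at least 2-fold lower, around a median log2 difference of -0.018. Of the 323 genes past 2-fold that had 2 or more probe sets past the filter, 305 had all of them in the same direction and 18 did not.

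**Figure D1:**
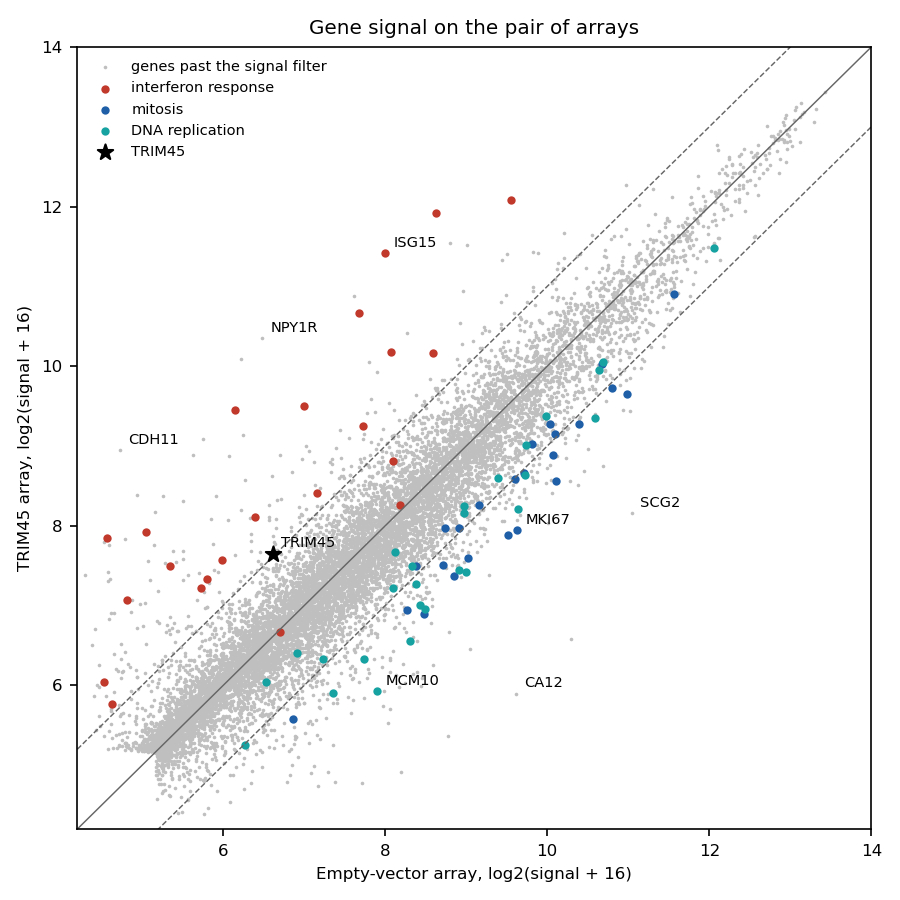
Each point is a gene past the signal filter, with its log2(signal + 16) on the empty-vector array (x axis) and on the TRIM45 array (y axis), 1 array each; the solid line marks equal signal and the dashed lines a 2-fold difference. Interferon response genes (red) lie mostly above the upper dashed line, mitosis (blue) and DNA replication (teal) genes lie below the solid line, and TRIM45 (star) is 2.05-fold higher.

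The genes with the largest higher values on the TRIM45 array included 5 that interferon induces. ISG15, a ubiquitin-like modifier, read 2740.4 against 238.5 (10.7-fold), IFI6 3889 against 375 (9.84-fold), IFI44L 692 against 54.6 (9.89-fold), and OAS1, a sensor of double-stranded RNA, 216 against 7.64. TRIM22, another member of the tripartite motif family and a known interferon target, read 321 against 14.4. The other 7 of the 12 were CDH11, encoding the adhesion molecule cadherin-11 (483 against 10.3), NPY1R, a neuropeptide Y receptor (1304 against 73.0, 14.6-fold), KRT15, a type I keratin (1082 against 58.3, 14.6-fold), PARM1 (10.1-fold), TXNIP, an inhibitor of thioredoxin and of glucose uptake (9.61-fold), NRN1, encoding neuritin (9.53-fold), and PNMA8A (203 against 8.08). On the empty-vector array OAS1, TRIM22, CDH11 and PNMA8A read below the array median, where signal cannot be told from background, so the size of their difference depended on the pseudocount. For CDH11 the log2 difference was 5.40 with a pseudocount of 1 and 2.87 with 64, and for OAS1 4.63 and 1.96. Of the others, NRN1 gave 3.73 and 2.41, PARM1 3.77 and 2.54, KRT15 4.17 and 3.21 and IFI44L 3.62 and 2.66. The 3 probe sets of TXNIP gave log2 differences between 2.74 and 3.27. Those of CDH11 spread from 1.26 to 4.23, so the size of its difference depended on the probe set. ISG15, IFI6, IFI44L, NPY1R, KRT15, TRIM22, NRN1 and PNMA8A each rested on 1 probe set. Of these 12 genes, 9 were again among the 12 highest with the mean of probe sets, 7 with a pseudocount of 1 and 9 with a pseudocount of 64. With gene-specific probe sets, which 8 of them have, 7 were.

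The genes with the largest lower values included CA12, a membrane-bound carbonic anhydrase (43.9 against 763, 13.2-fold lower), and the non-coding host gene MIR3681HG (80.6 against 1229, 13.1-fold lower). PADI3, a peptidylarginine deiminase, was 10.6-fold lower, and SCG2, encoding the neuroendocrine protein secretogranin II, 7.40-fold (271 against 2077). STRA6, the membrane receptor for retinol uptake, was 6.03-fold lower and ACOX2, a peroxisomal acyl-CoA oxidase, 5.69-fold lower. LRATD2 was 5.48-fold lower. On the TRIM45 array CGNL1, a tight junction protein (14.3 against 276), PLAC8 (11.4 against 192), PLBD1 (11.8 against 149), CEMIP, a hyaluronan-binding protein (10.8 against 127), and SUSD2 (14.3 against 140) read below the array median, so their folds depended on the pseudocount. For CGNL1 the log2 difference was -4.20 with a pseudocount of 1 and -2.13 with 64. Of the others, PADI3 gave -4.02 and -2.44, ACOX2 -2.99 and -1.72, CA12 -4.11 and -2.95 and LRATD2 -2.78 and -1.83. The 6 probe sets of CA12 past the filter ranged from -4.01 to -0.065, the 2 of CGNL1 from -3.28 to -0.38, the 2 of LRATD2 from -2.45 to -0.014 and the 2 of SUSD2 from -2.38 to -0.35, each a disagreement larger than the pooled spread between probe sets. PADI3, PLAC8, SCG2, PLBD1 and ACOX2 each rested on 1 probe set, and MIR3681HG and CEMIP each had 1 past the filter. For STRA6 the gene-specific probe set, which lay below the signal filter, gave -0.40, and with the mean of all its probe sets MIR3681HG was at -1.26 and CEMIP at -1.27. The order of these genes depended on such choices: of the 12, 6 were again among the 12 lowest with the mean of probe sets, 10 with a pseudocount of 1 and 8 with a pseudocount of 64. With gene-specific probe sets, which 11 of them have, 10 were.

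Interferon response genes formed the group furthest from the rest. Of 23 measured members, 21 were at least 1.5-fold higher, none was at least 1.5-fold lower, and the median log2 difference was 1.72 (3.29-fold). That median lay above all 10000 random lists of equal size and signal, whose highest median was 0.32. Besides the genes named above, the antiviral effector IFIT1 (7.98-fold), the GTPases MX1 (log2 difference 2.88) and MX2 (2.25), IFI27 (2.54), IFIT3 (716 against 111), OAS2 (2.15), BST2 (2.11), the transcription factor subunit IRF9 (1.53) and the RNA sensors IFIH1 (1.54) and RIGI (1.26) were higher. The members between the limits were IFI35 (0.074) and USP18 (-0.032). Probe sets past the filter disagreed for OAS2, from -0.014 to 2.15, RIGI, from 0.063 to 1.81, and IFIT3, whose other probe set gave 1.25. MX1 (16.9) and MX2 (12.1) read below the array median on the empty-vector array, so the size of their differences depended on the pseudocount. Genes of MHC class I and antigen presentation had a median of 0.45 (percentile 100 of the random lists), with 5 of 14 members higher, among them HLA-B (1.21) and HLA-C (1.08), and 1 lower, the immunoproteasome subunit PSMB9 (-0.74). HLA-B and HLA-C are near-identical in sequence, so their probe sets may share signal. Neither has a gene-specific probe set, and over the 9 members that have one past the filter the median was 0.22 with either choice of probe set and the list did not stand apart. Among 28 other tripartite motif genes the median was 0.11 (percentile 98.0), with 5 higher and 2 lower. Of these, TRIM22 (3.45) and TRIM41 (1.03) were highest and TRIM16 (-0.76) and TRIM47 (-0.59) lowest. TRIM22 and TRIM41 have no gene-specific probe set, and over the 19 members that have one past the filter the median was -0.033 with those probe sets and 0.00077 with the brightest ones. The list did not stand apart over those members or with a filter at the 75th percentile (0.095).

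Genes of cell division were lower on the TRIM45 array. All 24 mitosis genes were at least 1.5-fold lower, with a median log2 difference of -1.10 (2.14-fold lower), below the lowest of the 10000 random medians, -0.51. MKI67, the proliferation marker Ki-67, read 233 against 768 (3.20-fold lower), with its 4 probe sets between -1.68 and -0.94. The spindle assembly factor TPX2 was 3.08-fold lower, the kinases AURKB (-1.58), BUB1 (-1.48) and PLK1 (-1.29) followed, and the smallest differences were those of CDK1 (-0.65) and PTTG1 (-0.65). The 2 probe sets of AURKB read -1.58 and -0.40, and the 4 of CDK1 ranged from -1.38 to -0.65. Of 27 DNA replication genes, 23 were at least 1.5-fold lower and none was higher, with a median of -0.90 (1.87-fold lower) against a lowest random median of -0.38. MCM10, a replication initiation factor, was 3.93-fold lower (log2 difference -1.37 with gene-specific probe sets), and CDC6, which loads the MCM helicase, 3.35-fold lower. The helicase subunit MCM2 (-1.57), the thymidine kinase TK1 (-1.46) and the sliding clamp PCNA (-1.24) were also lower, while POLA1 (-0.48) and the transcription factor E2F1 (-0.45) lay within the 1.5-fold limit. On the same array the control probe sets for the 5′ end of ACTB read 267 against 542 and those for its 3′ end 4146 against 5065, so the TRIM45 array had less signal away from the 3′ end.

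Several stress and signalling lists were also lower. The control probe sets for the middle of GAPDH and ACTB gave log2 differences of -0.37 and -0.80. Whether the loss of signal away from the 3′ end on the TRIM45 array gave the lower list medians was not tested. The immediate early and ERK response list had a median of -0.26 (percentile 0.71), with 8 of 24 members lower and 2 higher. Its lower members included SPRY2, an inhibitor of receptor tyrosine kinase signalling (5.04-fold lower), the transcription factor ETV5 (3.73-fold lower, with its 4 probe sets from -1.90 to -0.63), MYC (-1.58) and the ERK phosphatase DUSP6 (-1.32), while SPRED1 (0.081) and ETV4 (-0.026) were near 0. EGR1 (1.17) and DUSP1 (0.59), both immediate early genes, were higher, although the 3 probe sets of EGR1 ranged from 0.43 to 1.34 and the mean of those of DUSP1, 0.17, lay within the 1.5-fold limit. This list did not stand apart with the mean of each gene's probe sets (-0.14), with no signal filter (-0.18) or without members that other lists hold (-0.18). Heat shock genes had a median of -0.53 (percentile 0.09), with 5 of 11 lower and none higher, led by the chaperones DNAJA1 (-1.05) and HSPD1 (-0.94, with its 4 probe sets from -1.71 to -0.068). Of 23 proteasome subunits 5 were at least 1.5-fold lower and none higher, but 22 were below 0, with a median of -0.44 (percentile 0.03). PSMD11 (-1.25) and PSMC3 (-1.13) were lowest, and PSMA2 read 0.051. NRF2 targets had a median of -0.46 (percentile 0.08), with 5 of 16 lower, among them the pentose phosphate enzyme TKT (-0.79, with its 3 probe sets from -2.09 to -0.79) and SRXN1 (-0.77), and 1 higher, ABCC1 (0.64, or 0.38 with the mean of its probe sets). With the mean of probe sets (-0.22) or over the 11 members with gene-specific probe sets past the filter (-0.29, or -0.26 with their brightest ones) the list did not stand apart.

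Genes of the extracellular matrix differed in both directions, with a higher median. Of 24 measured members 7 were at least 1.5-fold higher and 4 lower, and the median was 0.29 (percentile 99.99), which became 0.094 with the mean of each gene's probe sets. The collagens COL5A1 (7.04-fold), COL6A3 (1.74) and COL5A2 (1.16), fibronectin FN1 (1.53) and the protease inhibitor TIMP1 (1.00) were higher, whereas the basement membrane collagens COL4A1 (-1.24) and COL4A2 (-1.06) and the proteoglycan VCAN (-0.93) were lower. The 6 probe sets of FN1 ranged from 0.060 to 1.69 and the 3 of COL5A1 from 1.28 to 2.82, with 1.98 by its brightest at a pseudocount of 64, and COL6A3 read 9.18 on the empty-vector array, below the array median, so its log2 difference was 0.85 with a pseudocount of 64. Regulators of epithelial-mesenchymal transition had a median of 0.25 (percentile 98.7), with TWIST1 (1.19), the integrin ITGAV (0.95), CDH2 (0.79, with another probe set at 0.33) and SNAI2 (0.62, from signals near the array median) higher and S100A4 (-0.85) lower among 10 members. This list no longer stood apart without a signal filter (0.028) or with a filter at the 75th percentile. Among matrix proteases the median was 0.054 (percentile 81.4), with ADAM12 at 1.98 (1.15 with the mean of its probe sets) and ADAMTS1 at -2.35 (-1.69, or -1.65 with a pseudocount of 64). TGF-beta response genes had a median of 0.046 (percentile 81.8), with 6 of 17 higher and 1 lower, and stood apart as higher with a filter at the 75th percentile (0.29) or the mean of probe sets (0.11). Among them the inhibitors of basic helix-loop-helix factors ID2 (5.67-fold) and ID3 (2.74-fold) were higher, and the matricellular gene CCN1 (-0.89) was lower.

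**Figure D2:**
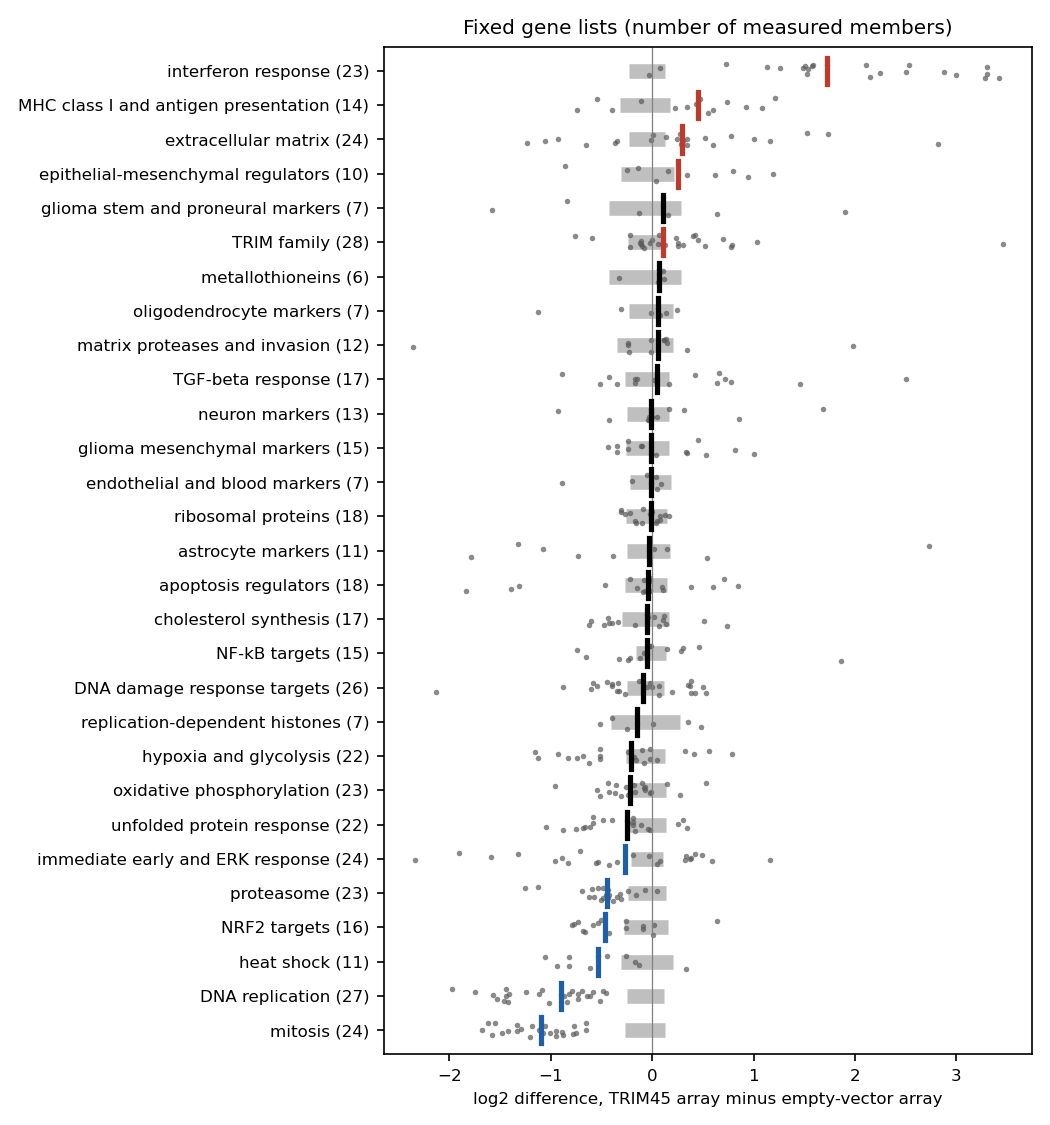
Each row is a gene list with its number of measured members; grey points are single genes (log2 difference, TRIM45 array minus empty-vector array), the thick vertical mark is the list median, and the grey band is the central 95% of the medians of 10000 random lists matched on size and signal. Marks are red where the list lay above the band, blue where below it and black otherwise; the interferon response median of 1.72 and the mitosis median of -1.10 lie furthest out.

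The list of DNA damage response targets did not stand apart, with a median of -0.087 (percentile 33.6), no member at least 1.5-fold higher and 4 of 26 lower. It holds target genes of that response and does not measure the response as a whole. CDKN1A, the cyclin-dependent kinase inhibitor p21, was 1.34-fold higher (345 against 249), MDM2, an E3 ubiquitin ligase, 1.25-fold lower, and PMAIP1, which encodes the pro-apoptotic protein NOXA, 1.45-fold higher. DDB2 (-0.88) and the stress cytokine GDF15 (-2.13) read lower. For GDF15 this rested on 1 probe set, since the other past the filter read -0.20 and the gene-specific one, below the filter, -0.0095. Regulators of apoptosis had a median of -0.043 (percentile 48.4), with 3 of 18 higher and 3 lower. The pro-apoptotic BCL2L11 (0.84) and the inhibitors of apoptosis XIAP (0.71) and BIRC2 (0.60) were higher by their brightest probe set. The pro-apoptotic BIK (-1.84) and BID (-1.39, with its 3 probe sets from -1.39 to -0.72) and the mitotic inhibitor of apoptosis BIRC5 (-1.31) were lower. The 5 probe sets of BCL2L11 ranged from -0.17 to 0.84, and with the mean of probe sets BCL2L11 (0.28) and XIAP (0.42) lay within the 1.5-fold limit. NF-kB targets had a median of -0.0505 (percentile 15.8) and a mean of 0.039, with the chemokine CXCL8 3.64-fold higher (log2 difference 1.15 with the mean of its probe sets) and ICAM1 (-0.74) and TNFAIP2 (-0.66) lower, the last 2 within the limit with the mean of probe sets (-0.34 and -0.39).

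Metabolic and housekeeping lists lay within the range of random lists. The unfolded protein response had a median of -0.24 (percentile 2.93), with 7 of 22 members lower, led by the transcription factor ATF4 (-1.04), and none higher. It stood apart after loess normalization or with a pseudocount of 64. Oxidative phosphorylation (-0.21, percentile 4.75), hypoxia and glycolysis (-0.20, percentile 6.84) and cholesterol synthesis (-0.048, percentile 50.2) did not stand apart, although the hypoxia-inducible genes ADM (-1.16) and ANGPTL4 (-1.13, with another probe set at -0.47) were lower and NDRG1 (0.79) was higher. Over the 11 members with gene-specific probe sets past the filter the hypoxia and glycolysis list stood apart as lower (-0.51). Ribosomal protein genes had a median of -0.014 (percentile 60.8) with all 18 members within 1.5-fold, replication-dependent histones -0.15 (percentile 23.4, 7 members) and metallothioneins 0.071 (percentile 76.6, 6 members). Histone and metallothionein genes are near-identical copies, so values of single members are uncertain.

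Markers of brain cell types gave no common shift. Astrocyte markers had a median of -0.033 (percentile 31.1), with the glutamate transporter SLC1A3 (-1.79, or -0.96 with the mean of its probe sets), the receptor FGFR3 (-1.32, or -0.66), S100B (-1.07, at 5.39 on the TRIM45 array, below the array median) and CLU (-0.73, with its 3 probe sets from -0.73 to -0.36) lower. The glutamine synthetase gene GLUL read 2.73 by the 1 of its 4 probe sets past the filter, but 0.016 by its gene-specific probe set, below the filter, and 0.76 by the mean of its probe sets, and its empty-vector signal, 8.26, lay below the array median. This list stood apart as lower with a filter at the 75th percentile (-0.56), over the 6 members with gene-specific probe sets past the filter (-0.53) or with the mean of probe sets (-0.14). Neuron markers had a median of -0.013 (percentile 53.8), with neurofilament NEFL (1.69, or 1.03 with the mean of its probe sets) and MAP2 (0.86) higher and ENO2 (-0.93) lower, although the other probe set of MAP2 read -0.014 and their mean, 0.42, lay within the limit. Oligodendrocyte markers (0.058, percentile 74.4) held 1 lower member, UGT8 (-1.13), and endothelial and blood markers (-0.014, percentile 36.0) held 1, ENG (-0.89, or -0.48 with the mean of its probe sets). Of 17 named microglia and macrophage markers only AIF1 passed the signal filter, at 37.7 on the TRIM45 array and 33.6 on the empty-vector array. Glioma stem and proneural markers had a median of 0.11 (percentile 85.9), with SOX4 (1.90, or 1.27 with the mean of its probe sets) and DLL3 (0.64, or 0.24 with the mean of its probe sets) higher and the intermediate filament nestin, NES (-1.58, with another probe set at -0.98), and SALL2 (-0.84) lower. Glioma mesenchymal markers had a median of -0.014 (percentile 57.0), with TIMP1 (1.00) and LGALS3 (0.81) higher and none of 15 lower. Median and mean differed in sign for the NF-kB, matrix protease (mean -0.019), neuron (0.12), oligodendrocyte (-0.13) and glioma mesenchymal (0.11) lists.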

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

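The checks of the control probe sets were planned, and the look at probe sets without a gene symbol was chosen after seeing the data. The array's own control probe sets, which give no gene its value, differed between the arrays. The ratio of the 3′ over the 5′ probe set of ACTB was 15.5 on the TRIM45 array against 9.35 on the empty-vector array, and that of GAPDH was 1.26 against 1.02. The middle ACTB probe set read 779 against 1346. The 9 hybridization spike-in probe sets read between 1.00 and 1.11 times the empty-vector signal (median 1.05), and the 12 poly-A spike-in probe sets between 0.76 and 1.06 times (median 0.92).

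Probe sets without exactly 1 gene symbol, which entered no gene value, also differed. Of 5046 past the filter, 67 (1.33%) were at least 2-fold higher and 60 (1.19%) at least 2-fold lower, against 1.86% and 2.61% of the 23217 probe sets with 1 symbol.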

How the results depend on the processing

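Scaling to the hybridization spike-in controls, no scaling, a minimum signal of 100 and the brightest probe set over genes that have a gene-specific one were tests chosen after seeing the data. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. The interferon response, mitosis, DNA replication, heat shock, proteasome and extracellular matrix lists stood apart in the same direction under all 13 alternatives, with medians from 1.34 to 2.18, -1.14 to -0.98, -1.05 to -0.72, -0.61 to -0.48, -0.49 to -0.39 and 0.094 to 0.35. The count of genes at least 2-fold higher and lower became 849 and 1369 at 1.5-fold, 92 and 70 at 3-fold, 172 and 246 with the mean of each gene's probe sets, and 146 and 191 with a pseudocount of 64, against 288 and 383; the thresholds and the pseudocount move these counts by construction, and for the mean of probe sets the cause was not tested. With a pseudocount of 64 the TRIM45 difference was 0.77 and the DNA replication median -0.72; with a pseudocount of 1 that median was -1.05 and the interferon response median 2.18. The interferon response median was 1.34 with a pseudocount of 64, 2.13 with the stricter filter, 1.53 with the mean of probe sets and 2.11 with gene-specific probe sets, where the mitosis median was -0.98. Gene-specific probe sets left 3 lists apart as higher instead of 5 and turned the median of the tripartite motif list to -0.033. They covered 9696 genes instead of 12658, without HLA-B, HLA-C, TRIM22 and TRIM41. With the brightest probe set over the same genes that median was 0.00077 and the same 5 lists changed their call (MHC class I, tripartite motif, NRF2, hypoxia and astrocyte), so these calls changed with the genes covered. The astrocyte list, within the random range above, was apart as lower with the stricter filter (-0.56), gene-specific probe sets (-0.53) and the mean of probe sets (-0.14). Of 62 named genes past 2-fold, 52 stayed past it with the mean of probe sets, 51 with a pseudocount of 64, 60 after quantile normalization and 59 with scaling to the hybridization spike-ins, and of the 44 that have gene-specific probe sets 39 did. With those, GLUL went from 2.73 to 0.016, GDF15 from -2.13 to -0.0095, STRA6 from -2.59 to -0.40 and CDH11 from 4.23 to 1.26. Among the lists that stood apart, only the tripartite motif median changed sign under any alternative. Several lists within the random range and near 0, such as apoptosis, neuron markers and ribosomal proteins, had medians on both sides of 0. Scaling to the hybridization spike-ins moved the median of all genes to -0.055. The poly-A spike-ins, with a median ratio of 0.92, differed in the other direction and were not used for scaling. Signal over background limits the dim genes: with a signal near 20, no level can be told from background here.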

Other observations

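The test of copy number, for which chromosome medians had already been seen, and the reading of other differences between the cultures were chosen after the result was seen. Several genes outside the naming rule, chosen after their values were seen, were related to groups above. All 4 inhibitors of basic helix-loop-helix factors were higher, with ID4 at 2.18 and ID1, a member of the TGF-beta response list, at 0.72 on the log2 scale beside ID2 and ID3. SPRY1 (-2.22), a paralog of SPRY2, was lower. The Cip/Kip inhibitors CDKN1B (0.57) and CDKN1C (1.17, with its 4 probe sets from 0.20 to 1.17) read above 0, as CDKN1A did. Non-coding RNAs of an imprinted locus, MEG3 (2.19, with its 7 probe sets from 0.032 to 3.36) and SNORD114-3 (2.61), were higher, and so were the interferon-induced genes CMPK2 (2.25), IFITM1 (2.14), SAMD9L (1.77) and HERC6 (1.66). SNORD114-3 and CMPK2 read below the array median on the empty-vector array, so the size of their differences depended on the pseudocount.

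Interferon response genes were higher by a median of 1.72. As to scaling as the whole source, the lowest median over 5 scalings and normalizations was 1.67. These put the median of all genes between -0.055 and 0.016, so steps of this size could hardly have removed 1.72. Admixed immune cells would bring their own abundant transcripts, but the 17 named microglia and macrophage markers had a median difference of 0.012 and none read above 37.7 on the TRIM45 array, where ISG15 read 2740.4. Subtracting the median of the 50 nearest genes left a median of 1.79, with members on 11 chromosomes. No run of 50 genes had a median above 0.31, so this subtraction was bound to leave most of the difference. An effect of TRIM45 and another difference between the cultures cannot be told apart, since there was 1 array per group.

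Mitosis and DNA replication genes together (51 genes) were lower by a median of -1.06. Over the 5 scalings and normalizations the median closest to 0 was -1.001, and after subtracting the neighbourhood median it was -0.996. The neighbourhoods themselves had a median of -0.048, and the scalings moved the median of all genes little. Both steps were thus bound to leave most of the difference. The steeper 3′ to 5′ signal of the TRIM45 array could lower many transcripts, and it stays open. That 10000 random lists of equal signal reached no further than -0.32 decides nothing, since both lists were taken up because they lay outside such lists, and no probe positions or transcript lengths were used. Slower division caused by TRIM45 and a denser or older culture at harvest cannot be told apart with 1 array per group.

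Neighbouring genes shifted together: on the autosomes, the rank correlation of the log2 differences of genes 20 places apart was 0.12 over 12225 genes, against at most 0.029 in 1000 shuffles, and at 40 places it was 0.088, as a description of these arrays, since genes are not independent replicates. Promoters or probe sets shared by directly adjacent genes would not reach that far, and loess normalization left 0.12. Clusters of related genes, which can span more places, were not left out. With genes past 2-fold left out, 16 of 22 autosomes had a median outside the central 95% of shuffles, where about 1.1 would be if genes varied independently. As neighbours vary together, this count is not a separate result. Medians over all genes ran from -0.20 on chromosome 21 and -0.16 on chromosome 22 to 0.082 on chromosome 7 and 0.086 on chromosome 5. The lowest run of 50 genes, from HEY1 to MTDH on chromosome 8, had a median of -0.63 with 44 genes lower. In 100 shuffles the lowest run was at -0.40. The highest run, from NHLRC3 to RNASEH2B on chromosome 13, had a median of 0.31 with 39 genes higher, against 0.20 in the shuffles. A candidate explanation is that the cultures differ in chromosome copy number, as diverged sublines of a cancer cell line may. Regional control of transcription stays open as well, and DNA of the same cells would be needed to decide. The different 3′ to 5′ signal of the arrays was not tested as a source.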
